A study of Mus musculus with 6 samples.

How the data were processed

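RNA from the lungs of 6 mice was hybridised to one-colour Agilent arrays, 1 array per mouse, 3 for saline and 3 for recombinant antithrombin. Groups and mouse numbers were taken from the sample titles. All 6 arrays lay on 1 slide and were scanned on 1 date, so neither could act as a batch, and the row of the array on the slide was tried as a block instead.

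The deposited scanner files hold spot intensity values, which per the file headers were made with Agilent Feature Extraction 10.7.3.1. Agilent Feature Extraction 9.1 is the version in the submitters' processing notes, and the difference was not resolved. The processed signal is a background-subtracted intensity with no scaling between arrays. The deposited value table holds log2 values per probe. Set against the scanner files, its columns equalled the log2 processed signal less a constant per probe and a shift per array, within 0.01 log2 for 100% of probes. The shift was removed before the comparison, so the check does not show how the arrays of the value table were scaled. The origin of the constant per probe is unknown, and that constant cancels in differences between groups. The column medians of the table ran from -0.0369 to 0.0763.

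The main values were log2 processed signals less the 75th percentile of each array over its non-control probes. Control spots and spots marked as outliers were left out, and spots of the same probe were averaged. The 59305 non-control spots held 56605 probes. The accession in the files was matched without its version to RefSeq transcripts of assembly GRCm38.p6, which named 32994 probes and left 23611 unnamed here. The array design names another build, so the reference served for names only and no coordinates are given. Each symbol was represented by the probe with the highest mean over all arrays, and unnamed probes were kept singly. A gene was tested if well above background on at least 3 arrays, which left 32447, of which 17514 had symbols. Of 68 further detected probes of named genes, 66 had the sign of the probe used.

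Differences, antithrombin minus saline, were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Standard errors and 95% intervals are from that fit. Where a probe was not well above background on any array of a group, a fold is given as a lower bound. It sets the mean of the brighter group against the mean, in the dimmer group, of the higher of the probe's own value and the lowest value among well detected probes of each array. Gene lists were tested with camera of limma at a preset correlation of 0.01, adjusted over the 41 lists, each of which had at least 5 tested members. Of 1023 list genes 973 were tested. A list score is the mean over members of the log2 signal less the saline mean.

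The groups, tests, gene lists, alternatives and the rule for named genes were set before the data were examined. The rule took up to 12 genes per direction that passed the adjusted threshold without overlap between groups, leaving out clone and model names. Free places went to the largest differences with an unadjusted p under 0.01, no overlap and detection on all arrays of the higher group. It also took 30 fixed genes and, from each list, the 4 tested members with the smallest p. Some genes that the rule took are not reported here.

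Alternatives were normexp background correction with an offset of 50, quantile normalisation, median scaling, no filter and a stricter filter on dim probes, all probes singly, the mean of detected probes, the deposited value table, a trended and robust variance, array weights, the mouse number or the array row as a block, leaving out each mouse, and for lists an estimated correlation, fry and ranks. Normexp used the median pixel signal with the median local background. With an estimated correlation, camera also tests on the 4 residual degrees of freedom of the fit, so it has little power for any list. The tests were tested on simulated data made from the means and spreads of the 32447 genes. Of 100 genes changed 2-fold 43 were recovered, and of 100 changed 4-fold 79 were, with 4 unchanged genes called. Of 4 lists shifted by 0.5 log2 all 4 were called, and 1 unshifted list was called. The simulated genes were drawn independently, while the estimated correlation in the real data was 0.79 for the cell cycle list. The simulation therefore cannot show how often unchanged genes or unshifted lists are called when genes move together. Figures were drawn with matplotlib 3.10.9.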

Results

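Lung RNA was measured in 6 male mice that had received an intraperitoneal injection of lipopolysaccharide, the bacterial outer membrane component that sets off endotoxin shock, at 20 mg/kg after 16 h without food. The mice were 10 weeks old, and lungs were taken at 30 h. At 3 h and again at 24 h, 3 mice had received recombinant antithrombin at 750 IU/kg and 3 had received saline. Antithrombin is the plasma inhibitor of thrombin and binds the heparan sulfate of the vascular glycocalyx. Each label names a separate mouse, so n counts mice. No mouse without lipopolysaccharide was analysed here, so each value compares antithrombin with saline under endotoxin. Between 69.8% and 72.1% of the probes on an array were well above background, and no spot was saturated. The number of arrays limits the precision of every value below.

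The arrays parted by treatment except for saline mouse 2. The first principal component held 51.9% of the variance, and saline mice 1 and 3 lay at -48.3 and -62.4 on it, the antithrombin mice between 24.9 and 49.5, and saline mouse 2 at 7.86. Across tested genes, which are not independent replicates, saline mouse 2 correlated with the antithrombin arrays at a mean Pearson r of 0.993 and with the other saline arrays at 0.989. The mean r was 0.994 within the antithrombin group, 0.990 within the saline group and 0.987 between groups.

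**Figure D1:**
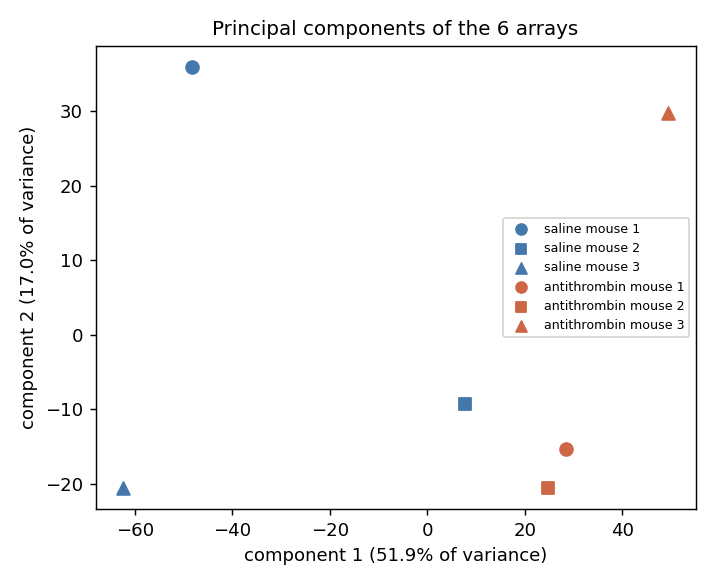
First and second principal components of the log2 signals of the tested genes, 1 point per mouse. Saline mouse 2 (7.86 on the first component) lies between saline mice 1 and 3 (-48.3 and -62.4) and the antithrombin mice (24.9 to 49.5).

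The comparison asks which lung transcripts differ when antithrombin is given after endotoxin. Calcb, which encodes the beta form of the neuropeptide calcitonin gene-related peptide, was 5.44-fold lower after antithrombin, with a mean log2 signal of -4.52 ± 0.06 (SD, n = 3) against -2.07 ± 0.08 (SD, n = 3) in saline mice. It was lower in each of the 3 antithrombin mice than in any saline mouse (limma, adjusted p = 0.00318). The noncoding transcript 4933411E08Rik rose, with a log2 difference of 1.46 (SE 0.10, limma adjusted p = 0.0464). It was dim, well above background on 1 of the 3 saline arrays and on 3 of 3 antithrombin arrays, and it is named here after its values were seen because it was the 1 gene that passed in that direction. These were the only 2 of 32447 genes and unnamed probes past the adjusted threshold with all 6 arrays, 1 higher and 1 lower.

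Many more genes had a small unadjusted p without passing the adjustment. At an unadjusted p under 0.05 there were 7016 genes, 2833 higher and 4183 lower, where 1622 would be due to chance if no gene differed. Of these, 380 were at least 2-fold higher and 348 at least 2-fold lower after antithrombin, against 87 and 87 with normexp background correction. The count of 7016 ran from 4206 without saline mouse 3 to 10321 without saline mouse 2. Other ways to part the 6 arrays into groups of 3 gave 385 to 3452 genes at that p. Genes move together across arrays, so a count above 1622 does not by itself show a treatment difference. The 3 values of one group lay beyond those of the other for 28.9% of genes, where chance gives 10%. The smallest adjusted p that missed the threshold was 0.105.

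The count of genes past the adjusted threshold rested on saline mouse 2. Without that array, 1510 genes were higher and 1911 lower at an adjusted p under 0.05 (limma), 815 were at least 2-fold higher and 764 at least 2-fold lower at an unadjusted p under 0.05. Saline mouse 2 was the saline array nearest the antithrombin arrays, so leaving it out tends by itself to widen the gap between groups. Counts without saline mouse 2, here and below, are therefore no separate support for a difference. Without saline mouse 3, 198 were at least 2-fold lower. The Calcb call ended without saline mouse 1 (adjusted p = 0.0514), antithrombin mouse 1 (0.0759), antithrombin mouse 2 (0.0611) or antithrombin mouse 3 (0.0574), within a range of 0.00108 to 0.282 over all alternatives. The 4933411E08Rik call held without saline mouse 2 (limma adjusted p = 0.0238). It ended without saline mouse 1 (0.298), saline mouse 3 (0.237), antithrombin mouse 1 (0.282), antithrombin mouse 2 (0.23) or antithrombin mouse 3 (0.353). Its adjusted p ran from 0.0222 to 0.353 over the alternatives in which it was tested. With normexp background correction the log2 difference was -1.43 for Calcb, which passed, and 0.23 for 4933411E08Rik, which did not (adjusted p = 0.168).

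Among genes with the largest separated differences, none of the following passed the adjustment (adjusted p between 0.105 and 0.161). Serpinb2, which encodes the plasminogen activator inhibitor PAI-2, had a log2 difference of 2.44 (SE 0.68), and Saa4, of the serum amyloid A family, 2.15 (SE 0.18). Slamf8, a receptor of myeloid cells, stood at -0.01 ± 0.03 (SD, n = 3) after antithrombin and at -1.71 ± 0.36 (SD, n = 3) after saline. Tdrkh differed by 2.51, Ankle1 by 2.12, Hpca by 2.05, Gmnc by 1.80, Pcdhga5 by 1.80 and Dleu2 by 1.68 on the log2 scale. Saa4, Hpca and Pcdhga5 were well above background on 1 of 3 saline arrays and Tdrkh on 2 of 3, so their differences rest in part on signal near background. Another Hpca probe gave 0.43, and other Ankle1 probes 1.13 and 1.36. Cd209e, Rslcan18 and Dgkb were not well above background on any saline array and were at least 1.59-fold, 1.80-fold and 1.51-fold higher after antithrombin. On the lower side, the log2 difference was -2.84 for Doc2b, -2.47 for Lrrc66, -2.44 for Potegl, -2.40 for Abca6, -1.92 for Hao1, -1.90 for Tex45, -1.81 for Atp13a5 and -1.81 for Galnt15. Potegl, Hao1, Tex45 and Atp13a5 were well above background on 1 of 3 antithrombin arrays, so their differences too rest in part on signal near background, and another Abca6 probe gave -0.73. Kcnf1, Npc1l1 and Ppef1 were not well above background on any antithrombin array and were at least 1.63-fold, 2.64-fold and 2.20-fold lower there.

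Transcripts of inflammatory cytokines and chemokines rose as a group after antithrombin. Of 36 tested members 30 had a positive difference, the median log2 difference was 0.67, and the list passed the camera test (adjusted p = 3.73e-09), although not with an estimated correlation (adjusted p = 0.825). Adjusted over the list alone, 13 members were higher and 1 lower, against 0 over all genes tested (limma; 18 higher and 1 lower at an unadjusted p under 0.05). The monocyte attractants Ccl7 and Ccl2 had log2 differences of 1.30 (SE 0.17) and 1.20 (SE 0.16), the neutrophil attractant Cxcl3 1.23 (SE 0.23), Ccl3 1.04 (SE 0.19) and the alarmin Il33 0.96 (SE 0.17). Saline mouse 2 scored 0.33 on this list, nearer to the antithrombin mice (0.53 to 0.71) than to saline mice 1 and 3 (-0.14 and -0.19). Without it the median was 0.89, and 15 members were higher and 1 lower adjusted over all genes. Markers of neutrophils were higher alongside, by a median of 0.44.

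Cell cycle transcripts had the smallest list p. All 38 tested members had a positive difference, with a median log2 of 0.56 (camera adjusted p = 6.14e-18), and with an estimated correlation the adjusted p was 0.825. Adjusted over the list alone 29 were higher, against 0 over all genes (limma; 31 at an unadjusted p under 0.05) and 14 over all genes without saline mouse 2. The mitotic genes Bub1, Pbk, Top2a and Birc5 had log2 differences of 0.90, 1.05, 0.92 and 0.64. Markers of neutrophils moved the same way, with a median log2 difference of 0.44 over 29 tested members (camera adjusted p = 1.3e-06, and 0.825 as the adjusted p with an estimated correlation). Adjusted over the list alone 0 members of the neutrophil list passed (limma; 9 higher at an unadjusted p under 0.05), and without saline mouse 2, 11 passed over all genes. Padi4 (0.95), the granule gene Camp (1.21), Cxcr2 (0.67) and Mmp8 (0.79) had the smallest p among them, while S100a8, among the most abundant of them, differed by 0.29 (SE 0.17). Saline mouse 2 scored 0.44 on the neutrophil list, within the range of the antithrombin mice.

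Heat shock and unfolded protein response transcripts rose, with a median log2 difference of 0.33 over 29 members (camera adjusted p = 1.3e-06, and 0.825 as the adjusted p with an estimated correlation). Adjusted over the list alone 9 were higher and 2 lower, against 0 over all genes (limma; 14 higher and 2 lower at an unadjusted p under 0.05). Without saline mouse 2, 7 were higher and 2 lower over all genes. The endoplasmic reticulum proteins Creld2, Pdia4 and Pdia6 had log2 differences of 0.71, 0.87 and 0.53, and the stress transcription factor Atf3 1.37. The list of smooth muscle and pericyte markers was higher by a median of 0.34 over 24 members (camera adjusted p = 0.000501, and 0.496 as the adjusted p with an estimated correlation). Of these, 3 passed adjusted over the list alone and 0 over all genes (limma; 7 at an unadjusted p under 0.05), or 5 over all genes without saline mouse 2. The median of the smooth muscle and pericyte markers was 0.21 without saline mouse 3. Lmod1, not well above background on any saline array, was at least 2.08-fold higher, the contractile gene Cnn1 had a log2 difference of 1.42, Myh11 0.71 and Acta2 0.52. Ciliated cell markers were higher by a median of 0.29 over 24 members (camera adjusted p = 0.000501, and 0.835 as the adjusted p with an estimated correlation), with Dnah5 at 0.60, Tppp3 at 0.44, Dnaic2 at 0.70 and Dnaic1 at 0.40, and 0 members passed adjusted over the list alone (limma; 8 higher and 1 lower at an unadjusted p under 0.05). Another Dnaic2 probe gave 0.14. Saline mouse 1 scored -0.26 on the ciliated cell markers against 0.10 and 0.15 in the other saline mice, and without it the median was 0.12 (adjusted p = 0.02, range over alternatives 3.58e-06 to 0.835). That mouse was also the lowest saline mouse on the club and secretory cell markers (-1.06 against 0.68 and 0.38), on cardiac and striated muscle (-0.91 against 0.29 and 0.62) and on adipocyte markers (-0.60 against 0.40 and 0.19).

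Glucocorticoid and fasting response transcripts fell. Of 28 tested members 27 had a negative difference, with a median log2 of -0.42 (camera adjusted p = 9.35e-06, and 0.835 as the adjusted p with an estimated correlation). Adjusted over the list alone 0 passed (limma; 13 lower at an unadjusted p under 0.05), and without saline mouse 2, 5 were lower over all genes. Ddit4 differed by -1.34 (SE 0.33), the phosphatase gene Dusp1 by -0.68 (SE 0.18), Arrdc2 by -0.85 (SE 0.26) and the fatty acid oxidation gene Cpt1a by -0.37 (SE 0.11). The circadian clock list was lower by a median of -0.45 over 18 members (camera adjusted p = 0.0122, and 0.835 as the adjusted p with an estimated correlation). Nr1d1 differed by -1.48 (SE 0.44), Dbp by -0.98 (SE 0.36), Ciart by -0.93 (SE 0.33, another probe -0.27) and Tef by -0.67 (SE 0.19), and 0 members passed adjusted over the list alone (limma; 7 lower at an unadjusted p under 0.05). The clock call ended without saline mouse 3 (median -0.28, adjusted p = 0.0539, range over alternatives 0.000925 to 0.835), and without saline mouse 2, 6 members were lower over all genes. Alveolar type 1 cell markers were lower by a median of -0.28 over 19 members (camera adjusted p = 0.00921, and 0.825 as the adjusted p with an estimated correlation), and 2 passed adjusted over the list alone, Gprc5a (-0.67) and Hopx (-0.52), against 0 over all genes (limma; 8 at an unadjusted p under 0.05) and 4 without saline mouse 2. Krt7 stood at -0.45 and Col4a3 at -0.42.

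The calls of the other 6 lists past the threshold each ended when at least 1 mouse was left out. In the interferon response list the antiviral genes Oasl2 (0.77), Oas3 (0.95) and Oas1a (1.01) and the chemokine Cxcl10 (0.97) were among 5 members higher adjusted over the list alone. That list passed camera at an adjusted p of 0.0155, with 0.835 as the adjusted p with an estimated correlation, and its median of 0.09 became -0.13 without saline mouse 2 (adjusted p = 0.52, range over alternatives 2.93e-05 to 0.835), whose score was -0.58 against 0.22 and 0.35 in the other saline mice. The call also ended without antithrombin mouse 1 (0.0567) and with array weights (0.229), and the median was 0.19 without saline mouse 1 and 0.26 without saline mouse 3. The list of endothelial activation and adhesion rose by a median of 0.11 (camera adjusted p = 0.0192, and 0.825 as the adjusted p with an estimated correlation), with 3 of 23 members past the list alone, among them Ccl2 and the endothelial selectin Sele (1.30). Nos2, at 0.94, did not pass. The call of that list ended without saline mouse 3 (adjusted p = 0.0741) and with all probes tested singly (0.0558), in a range over alternatives of 0.000883 to 0.825, and the median was 0.07 without antithrombin mouse 1 and 0.16 without antithrombin mouse 2.

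The list of cardiac and striated muscle transcripts was higher by a median of 0.47 (camera adjusted p = 0.00988, and 0.835 as the adjusted p with an estimated correlation). Saline mouse 1 scored -0.91 there against 0.29 and 0.62 in the other saline mice, and without it the median was -0.08 (adjusted p = 0.843). The call also ended without antithrombin mouse 2 (median 0.16, adjusted p = 0.161), the median was 0.86 without saline mouse 3, and the range over alternatives was 4.04e-06 to 0.843. Acta1 (0.76) was the 1 member past the list alone, and Actc1 (0.73), Ldb3 (0.60, another probe 0.23) and Myl7 (0.88) came next. B and plasma cell markers were higher by a median of 0.44 (camera adjusted p = 0.0147, and 0.835 as the adjusted p with an estimated correlation), and antithrombin mouse 3 scored 1.07 against 0.06 and 0.00 in the other antithrombin mice. That call ended without antithrombin mouse 3 (median 0.04, adjusted p = 0.908) and without saline mouse 3 (0.21, 0.0827), and with array weights (0.29, 0.0771), with a range over alternatives of 0.000439 to 0.908. Vpreb3, Fcer2a, Jchain and Spib had log2 differences of 0.53, 1.02, 1.01 and 0.78, and 0 members passed adjusted over the list alone (limma; 3 higher at an unadjusted p under 0.05). The platelet and megakaryocyte markers were higher by 0.38 (camera adjusted p = 0.0155, and 0.835 as the adjusted p with an estimated correlation), although 0 members were higher and 1, Gng11 (-0.31), was lower at an unadjusted p under 0.05 (limma), and 0 passed adjusted over the list alone. Gp1ba stood at 1.76, Itga2b at 1.24 and Clec1b at 0.78. That call ended without saline mouse 1 (adjusted p = 0.0912), saline mouse 3 (0.129) or antithrombin mouse 3 (0.0734), and without saline mouse 2 the median was 0.65 (7.29e-05). The list of hypoxia and glycolysis was higher by 0.21 (camera adjusted p = 0.0147, and 0.835 as the adjusted p with an estimated correlation), with 0 members past the list alone (limma; 5 higher and 3 lower at an unadjusted p under 0.05). Bnip3 stood at -0.44, Slc2a1 at 0.63 and P4ha1 at 0.61, and Ddit4 is also a member. That call ended without saline mouse 3 (median 0.12, adjusted p = 0.0827) or antithrombin mouse 1 (0.104), with a range over alternatives of 0.000572 to 0.835. Over all 41 lists the scores of the groups did not overlap in 10, where chance gives 10%, and 9 of these were among the 15 called. Of the 10 ways to part the 6 arrays into groups of 3, the real one included, 6 gave 15 or more lists.

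**Figure D2:**
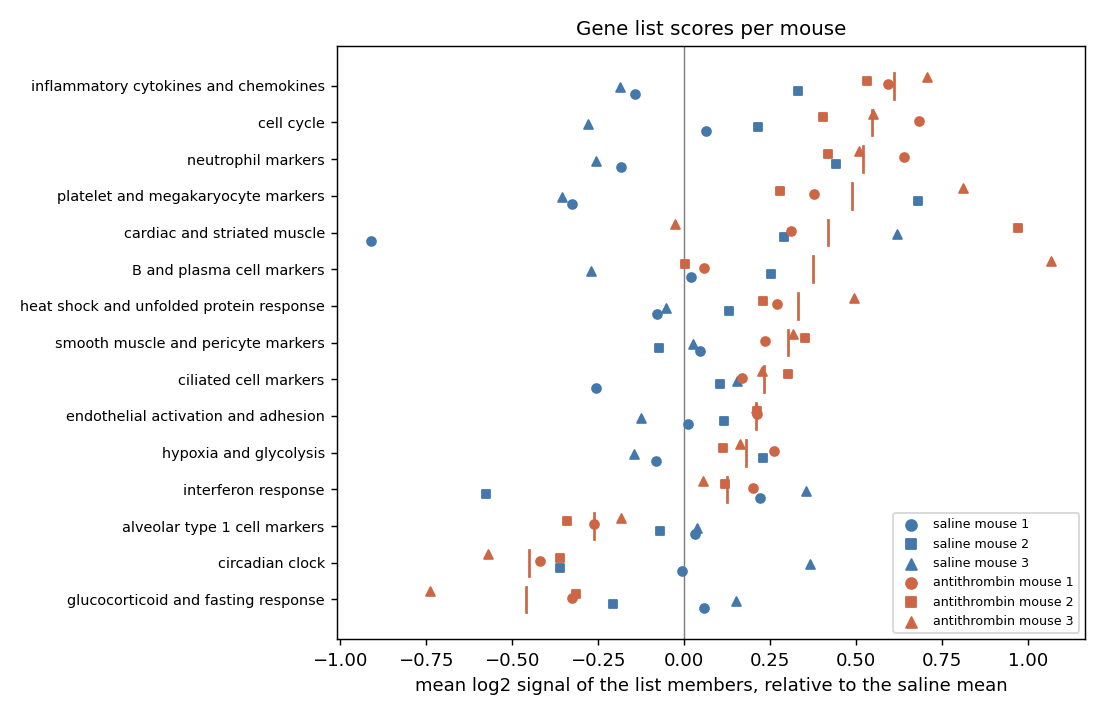
Mean log2 signal of the members of each of the 15 lists past the camera threshold, relative to the saline mean, 1 point per mouse, with a vertical bar at the antithrombin mean. Saline mouse 2 lies at 0.33 on the cytokine and chemokine list and at -0.58 on the interferon list.

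Of the 30 genes fixed in advance for the glycocalyx, coagulation, endothelium and inflammation, none passed at an adjusted p under 0.05 (limma), and 9 did at an unadjusted p under 0.05, all of them higher after antithrombin. These were Sele, Ccl2, Tnf (1.02, SE 0.27), Il1b (1.15, SE 0.47), Cxcl1 (1.19, SE 0.46), Cxcl2 (0.67, SE 0.18), the gelatinase Mmp9 (0.50, SE 0.17), the heparan sulfate cleaving enzyme Hpse (0.59, SE 0.22) and the hyaluronan synthase Has2 (1.61, SE 0.44). The values of the groups overlapped for Il1b, Cxcl1 and Hpse and not for the others. Of all genes tested, 21.6% had an unadjusted p under 0.05 (limma). Without saline mouse 2, 9 of the 30 passed, among them Ccl2, Cxcl1, F3 (lower, -0.54), Il1b, Il6, Mmp9, Sele and Tnf, with adjusted p from 0.0238 to 0.0481 (limma). Il6 had a log2 difference of 0.79 (SE 0.36) with all arrays. The 95% intervals of the log2 difference spanned 0 for the proteoglycan genes Sdc1 (-0.71 to 0.02), Sdc4 (-0.44 to 0.26), Gpc1 (-0.32 to 0.23) and Hspg2 (-0.27 to 0.36). They also spanned 0 for the anticoagulant receptors Thbd (-0.31 to 0.27) and Procr (-0.44 to 0.41), for tissue factor F3 (-0.79 to 0.12), Plat (-0.33 to 0.55) and for the antithrombin gene Serpinc1 (-0.56 to 0.86). Differences were 0.31 for Angpt1, 0.07 for Angpt2, -0.07 for Tek, -0.15 for Vwf, 0.24 for Selp, 0.11 for Icam1 and 0.02 for Vcam1, with adjusted p between 0.26 and 0.953. For Vcam1 another probe gave -0.06. Lcn2 stood at 8.74 ± 0.16 after antithrombin and 8.89 ± 0.13 after saline, and the surfactant gene Sftpc at 9.19 ± 0.20 and 9.27 ± 0.11 (SD, n = 3 each).

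**Figure D3:**
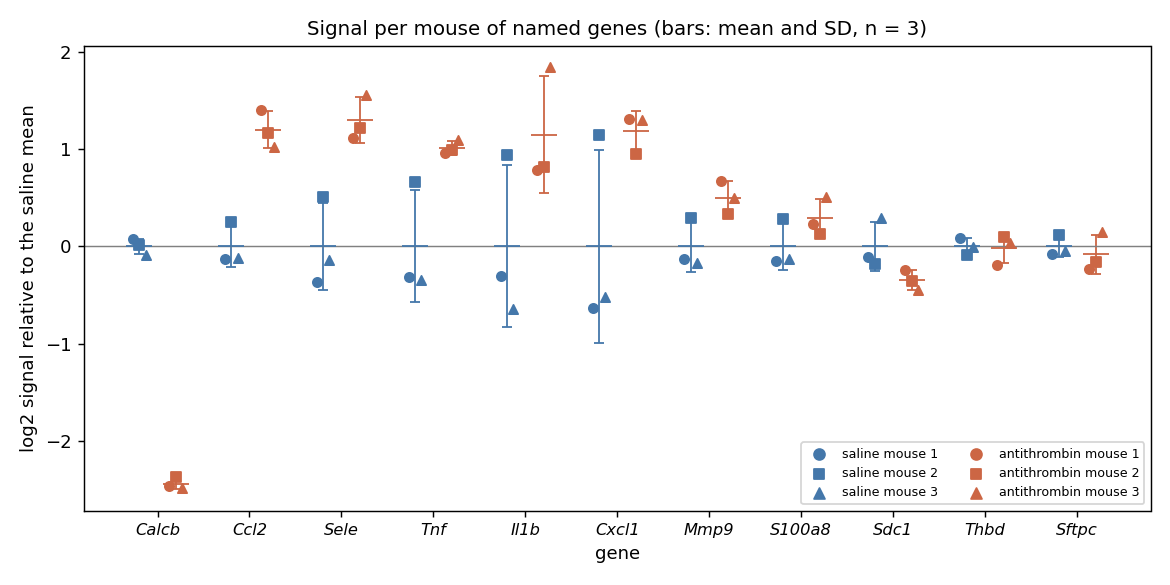
Log2 signal of 11 named genes relative to the saline mean, 1 point per mouse, with bars for the mean and SD of each group (n = 3). Calcb is lower in every antithrombin mouse, while for Tnf, Il1b and Cxcl1 saline mouse 2 lies above the other saline mice.

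The glycocalyx lists did not pass. Glycocalyx core proteins had a camera adjusted p of 0.923, with Vcan at 0.70, Podxl at 0.39, Esam at -0.32 and Sdc1 at -0.35. Glycosaminoglycan synthesis had 0.524, and 1 member passed adjusted over the list alone, the heparan sulfate polymerase gene Ext2 (-0.70), beside B3galt6 (0.86) and Xylt2 (-0.45). Glycocalyx degrading enzymes had 0.722, with Adamts4 at 0.75 and Hyal2 at -0.56. As set, that list also names the enzyme inhibitors Timp1, Timp2 and Timp3, so its result does not follow the enzymes alone. Coagulation and fibrinolysis had 0.17, with F13a1 at 0.78, F2r at -0.51 and Thbs1 at 0.55. Endothelial cell markers had 0.0947 and a median of -0.16, with 24 of 29 members negative, among them Erg (-0.55), Gpihbp1 (-1.65), Lyve1 (-0.95) and Robo4 (-0.45). Blood vessel growth signalling had 0.736, with Foxm1 at 0.53, Pdgfb at 0.80, Ephb4 at -0.44 and Fgf2 at -0.73, and epithelial and endothelial junctions 0.218, with Gja4 at -0.73, Cldn3 at -0.58, Pkp2 at 0.35 and Cldn18 at -0.33.

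Apart from the neutrophil, B and plasma cell, and platelet and megakaryocyte markers, lists of immune and blood cells missed the threshold. The camera adjusted p was 0.0947 for monocyte and macrophage markers, where the chemokine receptor gene Cx3cr1 had the smallest p (log2 difference 1.60), followed by F13a1, Vcan and Lyz2 (0.34), and the list passed without saline mouse 2 (0.0326). It was 0.914 for alveolar macrophage markers, with Lpl at -0.59, Cd9 at -0.25, Car4 at 0.32 and Krt79 at -0.33. It was 0.355 for T and NK cell markers, with Tcf7 at -0.59, Lef1 at -0.59 and Cd28 at -0.42, and Ctla4, not well above background on any antithrombin array, at least 2.00-fold lower there and the 1 member past the list alone. MHC class II and dendritic cell markers had 0.0947, with Bst2 at 0.38, Itgax at 0.51, Batf3 at 0.42 and H2-DMb2 at 0.68. Complement had 0.524, with Cd59a at -0.35, C5ar1 at 0.41, Cd55 at 0.27 and C7 at -0.33. Erythroid markers had 0.403, with Epor at -0.69, Tmcc2 at -0.29, Gata1 at 1.00 and Klf1 at -0.17.

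Epithelial and stromal lists gave no further call. The camera adjusted p was 0.698 for alveolar type 2 cell and surfactant genes, with Il33 past the list alone, Cxcl15 at 1.05, Scd1 at -0.50 and Sftpd at -0.30. It was 0.37 for club and secretory cell markers, with Cyp2b10 at -0.41, Scgb3a2 at 1.15, Cbr2 at -0.29 and Ltf at 1.20, and 0.266 for fluid and ion transport, where the sodium channel gene Scnn1a stood at -0.61 (another probe -0.22), Atp1b1 at -0.61, Slc26a4 at 0.53 and the water channel gene Aqp5 at -0.47. Extracellular matrix and fibrosis had 0.736, with Eln at -0.93 and Col6a3 at 0.88, where another probe gave 0.03, and Col15a1 at -0.55, where another probe gave 0.09. Fibroblast and mesenchymal markers had 0.878, with Gdf10 at -0.51, Col13a1 at 0.49, Meox2 at 0.29 and Pi16 at 0.58. Mesothelial markers had 0.809, with Tgm1 at 0.57, Upk1b at -0.73, Krt19 at -0.27 and Msln at -0.32, and adipocyte markers 0.305, with Pnpla2 at -0.67, Otop1 at -0.86, Adipoq at 1.87 and Adrb3 at -0.31.

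Among stress and metabolic lists, immediate early genes had a camera adjusted p of 0.0968, with Atf3 and Dusp1 leading, Myc at 0.59 and Egr3 at 1.56, and without saline mouse 2 the list passed (0.00588). Cell death and p53 targets had 0.815, with Eda2r (-0.80) past the list alone, Casp4 at 0.39, Trp53inp1 at -0.98 and Cdkn1a at -0.47. Acute phase and metallothioneins had 0.462, with Saa4 and Steap4 (0.83) past the list alone, Slc39a14 at 0.33 and Serpina3m at -0.42. Oxidative stress response had 0.518, with Sod2 at 1.19, Cbr3 at -0.68, Nqo1 at -0.74 and Slc7a11 at 0.65. Oxidative phosphorylation had 0.722, with Cycs at 0.38, Ndufv2 at -0.21, Cox4i1 at -0.22 and Ndufa4 at -0.16. Cholesterol and fatty acid synthesis had 0.141, with Pmvk at -0.83, Scd1 at -0.50 and Nsdhl at 0.40, and passed without saline mouse 2 (0.0155). The median, the mean and the camera direction differed in sign for 6 of the 41 lists, none of them among the 15 called: acute phase, glycocalyx degrading enzymes, blood vessel growth, extracellular matrix, cell death and alveolar macrophages.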

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

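None of the tests in this part was chosen after its result was seen. The deposited value table gave 1 gene higher and 1 lower, 379 and 345 genes past 2-fold, and 12 and 3 lists. The single higher gene was lost (0 genes) with normexp background correction, quantile normalisation, median scaling, no filter on dim probes, a filter on all arrays, all probes singly, a trended and robust variance, and the array row as a block, while array weights gave 2. Unadjusted p values under 0.05 (limma) numbered from 6208 to 8866 under the settings with 0 that were just listed. Calcb passed under each of these. The filter on all arrays left 4933411E08Rik untested, because it was well above background on 1 of 3 saline arrays. Normexp gave 87 genes at least 2-fold higher and 87 lower, no filter gave 620 lower, and a filter on all arrays 252 higher. The normexp setting adds an offset of 50 to each signal, which by itself shrinks the log2 differences of dim genes. The median processed signal of an array ran from 71.5 (saline mouse 3) to 81.3 (antithrombin mouse 2). Fewer dim genes can therefore reach 2-fold under normexp. How much of the drop the offset accounts for was not tested, nor was the cause of the changes with the filters. Leaving out each mouse gave 0 to 1510 genes higher, 0 to 1911 lower, 258 to 815 at least 2-fold higher, 198 to 764 at least 2-fold lower, and 0 to 9 fixed genes. The highest value of each range was without saline mouse 2. Lists numbered 8 to 14 higher and 3 to 4 lower. The interferon list turned to a median of -0.13 without saline mouse 2, in a range of -0.13 to 0.26 when each mouse was left out.

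With an estimated correlation camera called 0 lists higher and 0 lower (1 at an unadjusted p under 0.05), and fry called 0 and 0 (7 at an unadjusted p under 0.05). Of the called lists, cell cycle, cytokines and chemokines, heat shock, neutrophil, glucocorticoid, ciliated, smooth muscle and alveolar type 1 kept their call under all 19 camera settings that used the preset correlation. These settings share the preset of 0.01, so they do not test it. The estimated correlation of these lists ran from -0.01 for smooth muscle and pericyte markers to 0.79 for cell cycle. For smooth muscle and pericyte markers it lay below the preset, yet the camera adjusted p was still 0.496. Correlation alone therefore does not explain the lost camera calls. With an estimated correlation camera tests on 4 residual degrees of freedom, so a missed call there says little about a list. With the replicate block 0 genes were higher and 0 lower (5077 at an unadjusted p under 0.05), and 12 and 3 lists passed. Deviations of mice with the same number correlated at -0.01, -0.16 and -0.28, which gave no sign of pairing by number. Deviations within a group sum to 0, which ties these values to those of the other pairs, so they cannot exclude pairing. A slide or scan block was not run, because there was 1 of each. Signal over background limits the precision of dim genes, and 2-fold counts were not split by signal. Among named genes, values across all alternatives stayed on their side of the threshold 3478 times, came to pass 95 times, 94 of them without saline mouse 2, ceased to pass 18 times, and changed sign without passing 27 times.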

Other observations

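The tests below were chosen after the results were seen. That of glucocorticoid targets outside the lists was written before its own values were seen, but for a pattern that the list results had shown.

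The 6 arrays can be parted into groups of 3 in 10 ways, which is too few for a share under 0.05. The real split called 2 genes, and 2 of the 10 splits called as many, the highest other calling 4. For genes at least 2-fold different at an unadjusted p under 0.05 the real split gave 728 and the highest other 326, so 1 of 10 splits gave as many. The real split gave 87 higher and 87 lower with normexp background correction, under which the other splits were not run. For lists the real split gave 15, and 6 of the 10 splits gave as many, the highest other giving 17.

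Saline mouse 2 lay near the antithrombin arrays. A swap of labels between the groups would need an antithrombin array out of place, and 0 of them lay nearer to saline mice 1 and 3 than to their own group. The values also argue against the row of the array on the slide, since saline mouse 1 shares that row. Saline mouse 2 still correlated with antithrombin mice 1 and 2 by 0.00662 more (0.994 against 0.987). Within that row, saline mouse 2 lay in column 3, between antithrombin mice 1 and 2 in columns 2 and 4. Saline mouse 1 lay in column 1, so the row comparison does not cover neighbouring position, which was not tested. On an axis from saline mice 1 and 3 at 0 to antithrombin at 1, saline mouse 2 lay at 0.658. Held-out antithrombin mice lay between 0.816 and 1.19 with an SD of 0.206. The axis used the 1000 genes with the smallest limma p between its own ends. Neither saline mouse 1 nor 3 was held out, so 0 is not the position expected of a further saline mouse. A single wrong label therefore cannot be told apart from a saline mouse with a different course, which was not tested. The values of saline mouse 2 lay with the saline mice for Calcb (-2.06) and 4933411E08Rik (-6.34), but these genes were called with its label as given. Its interferon score of -0.58 lay below those of all other mice in either group.

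Chemokine and neutrophil lists were higher after antithrombin, and more neutrophils in the tissue may account for part of that. The 7 most abundant members of the neutrophil list differed by a mean log2 of 0.109 (SE 0.09) and the other 22 by 0.65 (SE 0.28). The 7 were S100a9, Lcn2, S100a8, Chil3, Csf3r, Retnlg and Fpr2. Lcn2 is also on the acute phase list and Chil3 on that of alveolar macrophages, so the 7 need not follow neutrophils alone. With the 5 most abundant the values were 0.04 (SE 0.07) and 0.62 (SE 0.27). Those gaps argue against the idea, but with the 10 most abundant members the values were 0.24 (SE 0.17) and 0.67 (SE 0.26), so the answer depends on a number picked after the values were seen. The explanation therefore stays open, as does a change in the neutrophils themselves, which was not tested.

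Glucocorticoid, fasting and clock lists were lower after antithrombin, and lower glucocorticoid action is a candidate explanation. The median of 12 glucocorticoid induced genes outside the lists was -0.34, with 10 of 12 lower, at the 0.01 percentile of 10000 random lists matched on signal, and all 3 antithrombin mice scored below all 3 saline mice, which chance gives, in either direction, for 10% of genes. Random lists ignore the correlation of real gene groups, and several of these genes, such as Sesn1, Pik3ip1 and Irs2, are also known to respond to feeding, so a difference in food intake stays open and untested. For a different time of day at collection, the opposite-phase clock genes Arntl and Nfil3 had a mean difference of 0.00419 (SE 0.11), below the 0.62 that a shift was taken to need, which goes against it. It is left as one that cannot be told apart because that bound assumes an amplitude and rests on 2 genes, and the requirement of at least 3 was set after these values were seen.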
